A study of Homo sapiens with 5 samples.

How the data were processed

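RNA was measured in 5 libraries of HCT116, a human colorectal carcinoma cell line, in a derivative that the series describes as a Dicer knockout. Dicer is the ribonuclease that releases mature microRNAs from their precursors. Per the labels, 1 library came from cells transfected with a negative control, 1 from cells with native let-7a, 1 with methylated let-7a (19A), 1 with native miR-17 and 1 with methylated miR-17 (13A). The labels give neither the kind of methyl group nor the sequences of the oligonucleotides. Position 19 of the human let-7a-5p sequence and position 13 of miR-17-5p, counted from the 5′ end, are both adenosines, and the label numbers were read as these positions. Per the labels' protocols, total RNA was extracted with Isogen and made into stranded, ribosomal RNA-depleted libraries with a TruSeq kit.

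The authors deposited 1 table of gene-level TPM (length-scaled transcript abundance) values, rounded to 1 decimal. Per the submitters' processing notes the genome build was hg19. The aligner, the counting tool and the annotation release are not given in the sources used here. Each column of the deposited TPM table sums to the same fixed total over 57773 gene identifiers, so the sequencing depth is unknown and read counts cannot be recovered. No confidence interval or detection floor is given for that reason. A TPM value is a share of the library, and a change in a few abundant genes shifts all others. Mitochondrial transcripts held between 9.36% and 12.6% of the TPM per library, and cytosolic ribosomal protein genes between 14.1% and 17.6%. How reads were assigned among overlapping or near-identical genes is not known, and a value of exactly 0 was not read as absence. Of the genes with a mean of at least 5 TPM, 23 were listed at 0 in at least 1 library, and 87.0% of these shared exons with another gene on the same strand, were pseudogenes, or had a retired or duplicated entry, against 19.6% of the genes above 0 in all 5 libraries.

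Each group holds 1 library. Differences between libraries therefore have no replicate check, and no p-value or standard deviation is given. The 6 comparisons, chosen before the data were examined like the gene lists, the filter, the 2-fold rule and the seed-site search, were each of the 4 microRNA libraries against the control and each methylated form against its native form. All differences are differences of log2(TPM + 1), first library minus second, over 14177 genes with a mean of at least 1 TPM across the 5 libraries. The pseudocount of 1 understates the change of genes with low values. Genes with a difference of at least 2-fold in TPM + 1 were counted as a rule of size, which is not a test.

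To place a gene list, its median difference was compared with the medians of 10000 random lists of the same size matched on mean expression in 20 bins. The value reported for a list is its median minus the median of the random lists, and a list was called apart when it lay outside the central 95% of them. This percentile describes these libraries and is not a p-value across samples. Seed sites were searched in the longest annotated 3′ untranslated region (3′ UTR) of each gene in GENCODE 29, for 12002 genes with a 3′ UTR of at least 50 nucleotides. A site was a match to microRNA positions 2 to 8 (7mer-m8), or to positions 2 to 7 followed by an A (7mer-A1), and a site with both features was called an 8mer. GENCODE 29 uses another genome build than the deposited table, so it served for sequences and gene types alone, and no coordinates are given. Of the deposited gene identifiers, 90.6% were found in it. In an analysis added after the data were seen, a linear model across genes gave, for 16384 heptamers, the difference between genes with and without each heptamer, with terms for 3′ UTR length, 3′ UTR GC content and mean expression. Genes are not independent replicates, and the tests use the rank of a heptamer alone. For 1 heptamer, picked as the top of this model, the genes were later split at random into 2 sets of 6001, to find it in the first set and rank it in the second. Both sets had contributed to that pick, so the second set was not held out.

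A set of 2 target lists and 25 other lists was fixed. The target lists held 61 textbook let-7 targets, of which 53 passed the expression filter, and 60 textbook targets of the miR-17 family, of which 57 passed. The other lists covered RNA silencing machinery, N6-methyladenosine (m6A) writers, erasers and readers, interferon-stimulated genes, NF-kB inflammatory genes, p53 targets, G1/S and DNA replication genes, G2/M genes, replication-dependent histones, cytosolic ribosomal proteins, mitochondrially encoded mRNAs, nuclear oxidative phosphorylation genes, cholesterol synthesis, hypoxia and glycolysis, the ATF4 and unfolded protein response, heat shock, immediate early genes, Wnt and stem-like colon genes, colon epithelial differentiation, epithelial adhesion and keratins, mesenchymal and fibroblast genes, blood and immune cells, endothelium, the TGF-beta response, autophagy and lysosome, and microRNA host genes. Of 851 list entries, 842 matched a deposited symbol and 8 matched through their Ensembl identifier.

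Genes were named by a fixed rule. It took the 8 highest and 8 lowest genes per comparison with a mean of at least 5 TPM, the 5 lowest and 2 highest members of the microRNA's own target list, 3 members of every other list called apart, DICER1, and, between methylated and native forms, the 5 targets or seed-site genes lowest with the native form. Because most of the extreme genes were listed at 0 in some library, a further set was named after the values were seen, with the 10 lowest and 8 highest protein-coding genes per comparison that had a mean of at least 20 TPM, values above 0 in all 5 libraries and an annotated 3′ UTR. The text names part of the genes that these rules take, and some of the others are withheld and not reported here.

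Alternatives covered pseudocounts of 0.1 and 5, no filter and a mean of at least 5 TPM, a 1.5-fold threshold, rescaling to protein-coding genes, other site definitions, random lists matched also on 3′ UTR length, and the mean of the other microRNA's 2 libraries as reference in place of the control. The list method and the heptamer model were tested on simulated data. On simulated libraries of 14177 genes, 20 of 20 lists of 40 genes lowered by 0.4 (log2), 16 of 20 lowered by 0.2 and 7 of 20 lowered by 0.1 fell below the central 95%, and 0 of 20 unchanged lists did. The simulated genes varied independently and list members were drawn at random. The 0 of 20 is therefore no error rate for lists whose genes vary together. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used.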

Results

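The study asked how methylated microRNAs affect the degradation of their target mRNAs. Total RNA was profiled in 5 libraries of Dicer-knockout HCT116 colorectal carcinoma cells, 1 each for a negative control, native let-7a, methylated let-7a, native miR-17 and methylated miR-17. The negative-control library listed 14227 genes at 1 TPM or more, native let-7a 14249, methylated let-7a 14233, native miR-17 14396 and methylated miR-17 14173. Sequencing depth is unknown, and with 1 library per group no difference given here has a replicate check. Across genes, the library pairs correlated with Pearson's r of log2(TPM + 1) from 0.974, for the control and methylated miR-17, to 0.989, for native and methylated miR-17. DICER1 had 15.4 TPM in the control, 11.2 with native let-7a, 12.5 with methylated let-7a, 15.9 with native miR-17 and 12.9 with methylated miR-17. No library of cells with intact Dicer was analysed here, so these levels do not check the knockout.

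Native let-7a against the control asked which transcripts the unmodified microRNA lowered. HMGA2, a chromatin architectural protein and textbook let-7 target, had 56.0 TPM in the control and 23.9 TPM with native let-7a, a 2.29-fold lower TPM + 1. PLAGL2, a zinc finger transcription factor, went from 26.5 to 13.7 TPM, IRS2, an insulin receptor adaptor, from 25.9 to 13.8 TPM, and PBX3, a homeobox cofactor, from 9.0 to 4.7 TPM. Of the 53 known let-7a targets tested, 41 were lower and 11 higher than in the control, and their median lay 0.25 (log2) below that of matched random lists, at percentile 0.0. All list values below are given in this way, relative to matched random lists. CPEB2 and ONECUT2 were the 2 highest members, with 3.1 against 1.8 TPM and 4.0 against 3.1 TPM. The list of known miR-17 targets was also apart with native let-7a (-0.10, 37 of 57 lower). The let-7a target list also lay below random lists in the miR-17 libraries against the same control, at -0.16 with native and -0.16 with methylated miR-17. Of the 53 members, 26 have a miR-17 site in an annotated 3′ UTR (49.1%, against 33.1% of all searched genes). HMGA2, which was also below the control in both miR-17 libraries, has up to 4 such sites. Whether these sites contribute to the values in the miR-17 libraries was not tested. With the mean of the miR-17 libraries as reference in place of the control, the list value was -0.04 at percentile 17.8 and was no longer apart.

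Genes with a let-7a seed site in the 3′ UTR, 2129 of the 12002 searched, had a median difference of -0.08 in native let-7a, against 0.0 in matched random lists. The median was 0.015 for the 9873 genes without a site. Of the genes with a 7mer or an 8mer site, 61.9% and 62.8% were below 0, and of the 54 searched genes that were at least 2-fold lower, 4 had a let-7a site (7.4%, against 17.7% of all searched genes). Matching the random lists on 3′ UTR length as well moved the seed-site value from -0.08 to -0.04, still outside the random lists. In the later heptamer model, the let-7a matches TACCTCA and CTACCTC ranked 1 and 3 from the lowest of 16384 with native let-7a. GGAGGGG, which is not a let-7a match, ranked 2. With methylated let-7a against the control, TACCTCA and CTACCTC ranked 17 and 7. HMGA2 has 0 let-7a sites in its longest annotated 3′ UTR, the one searched, and up to 7 in another annotated 3′ UTR.

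Of the lists other than microRNA targets, hypoxia and glycolysis genes were the furthest from random lists with native let-7a. Of 31 members 30 were lower with native let-7a, 8 of them at least 2-fold, and the list lay at -0.75. ANGPTL4, a secreted lipase inhibitor, went from 57.5 to 12.7 TPM, the glucose transporters SLC2A3 and SLC2A1 from 21.6 to 5.8 and from 608.6 to 235.7 TPM, and the carbonic anhydrase CA9 from 3.7 to 0.6 TPM. TGF-beta response genes lay at -0.42, with 16 of 19 lower, among them SMAD7 (14.2 to 5.4 TPM) and BAMBI (52.4 to 23.2 TPM). Wnt and stem-like colon genes lay at -0.34, with NOTUM, a secreted Wnt deacylase, at 35.6 and 21.9 TPM, and immediate early genes at -0.19, with EGR1 at 111.9 and 77.3 TPM. Mesenchymal genes lay at -0.24, led by COL6A1 (151.9 to 89.1 TPM), and microRNA host genes at -0.14, with MIR31HG at 14.9 and 8.4 TPM. The 13 mitochondrially encoded mRNAs were all lower, at -0.37, with MT-CO1 at 18547.7 TPM in the control and 12058.7 TPM with native let-7a. With the miR-17 libraries as reference, a setting added for these lists after the data were seen, the hypoxia (0.08), TGF-beta (0.02), Wnt (-0.06), mesenchymal (-0.10), microRNA host (-0.09) and mitochondrially encoded (0.07) lists were no longer apart, and immediate early genes were apart in the opposite direction (0.25). The microRNA host list was also within the random lists when these were matched on 3′ UTR length (-0.096).

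Genes of the ATF4 and unfolded protein response were higher with native let-7a, with 28 of 30 members above the control and a list value of 0.32. The cystine transporter SLC7A11 went from 27.5 to 57.5 TPM (47.1 to 60.6 TPM in all 4 microRNA libraries), the glutathione-degrading enzyme CHAC1 from 59.6 to 104.2 TPM and asparagine synthetase ASNS from 194.9 to 320.1 TPM. The 3′ UTR of SLC7A11 holds the heptamer GGTTGTG, and genes with it were relatively low in the control, as described under the other observations. The p53 target list lay at 0.13, with the stress cytokine GDF15 at 357.9 and 778.5 TPM, and interferon-stimulated genes also at 0.13, with IFI6 at 61.5 and 98.3 TPM. G2/M genes lay at 0.15, with 32 of 34 higher, and the kinetochore gene CENPF at 47.2 and 61.0 TPM. G1/S genes lay at 0.10, nuclear oxidative phosphorylation genes at 0.10 and cytosolic ribosomal protein genes at 0.09. With the miR-17 libraries as reference, interferon-stimulated (-0.17), G1/S (-0.20), oxidative phosphorylation (-0.09) and ribosomal protein (-0.055) genes were apart in the opposite direction, and p53 targets (0.09) were no longer apart. With a pseudocount of 5, G1/S (0.06) and interferon-stimulated (0.08) genes were within the random lists. In all, 172 genes were at least 2-fold higher and 167 lower, a total of 339 that became 626 with a pseudocount of 0.1 and 80 with 5, and the counts of the other comparisons depended on the pseudocount in the same way. Among protein-coding genes of at least 20 TPM, the largest increases were CACUL1 (28.7 to 76.0 TPM), MNAT1 (10.4 to 24.8 TPM) and the endoplasmic reticulum chaperone CANX (287.2 to 631.3 TPM), which were higher by similar amounts in the other microRNA libraries. Several of the most extreme values belonged to genes listed at 0, such as the readthrough gene RPL36A-HNRNPH2, at 26.1 TPM in the control and listed at 0 with native let-7a, and ESR1, at 12.6 TPM in the control and listed at 0 with native let-7a alone.

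Methylated let-7a differed from the control by smaller amounts in HMGA2, PLAGL2 and IRS2. These targets were named for low values with native let-7a, which alone would favour smaller amounts here. HMGA2 had 28.1 TPM, PLAGL2 17.0 TPM, IRS2 17.4 TPM and the RNA-binding protein IGF2BP2 98.5 TPM, a log2 difference from the control of -0.60. The known targets lay at -0.17, with 42 of 53 lower, and genes with a let-7a seed site at -0.03 (percentile 0.0), with a median difference of -0.08 as with native let-7a and of -0.04 for genes without a site. With the miR-17 libraries as reference the seed-site value was -0.005 at percentile 24.2 and the target-list value turned to 0.06. Neither was apart on that reference. Against the control, the let-7a seed-site genes lay at -0.04 (percentile 0.0) in methylated miR-17 and at -0.004 (percentile 23.64) in native miR-17. These random lists were not matched on 3′ UTR length. In the heptamer model, which holds 3′ UTR length, CTACCTC and TACCTCA had coefficients of 0.0362 and 0.0254 in methylated miR-17. Hypoxia and glycolysis genes lay at -0.29, with 29 of 31 lower and 0 of them at least 2-fold, and ANGPTL4 had 32.8 TPM. TGF-beta response genes lay at -0.32, with BAMBI at 27.2 against 52.4 TPM, Wnt and stem-like genes at -0.17 and immediate early genes at -0.16. ATF4 and unfolded protein response genes lay at 0.20, with the chaperone cofactors CRELD2 and MANF at 42.9 against 27.0 and 200.2 against 146.1 TPM. Ribosomal protein genes lay at 0.16, interferon-stimulated genes at 0.14, p53 targets at 0.09 and nuclear oxidative phosphorylation genes at 0.08. The mitochondrially encoded mRNAs (-0.10, percentile 2.91), G2/M genes (-0.05), G1/S genes (-0.03), mesenchymal genes (-0.05) and microRNA host genes (-0.07) stayed within the random lists. With the miR-17 libraries as reference, hypoxia (0.59), immediate early (0.27), interferon-stimulated (-0.21) and oxidative phosphorylation (-0.11) genes were apart in the opposite direction, and TGF-beta (-0.035), Wnt (0.08), ATF4 (-0.005), ribosomal protein (0.001) and p53 (0.03) genes were no longer apart. With a mean of at least 5 TPM, the mesenchymal (-0.32) and mitochondrially encoded (-0.125) lists were apart. There were 166 genes at least 2-fold higher and 139 lower.

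Methylated against native let-7a asked how the methyl group changed the response. Known let-7a targets were higher with the methylated form, 37 of 53 members, with the list at 0.15, outside the central 95% of random lists. IRS2 had 17.4 against 13.8 TPM and IGF1R, the insulin-like growth factor receptor, 7.9 against 6.1 TPM, while IGF2BP3 (10.4 against 14.4 TPM) and HIC2 (3.2 against 4.6 TPM) were lower. Genes with a let-7a seed site lay at 0.04, and at 0.016 with random lists matched also on 3′ UTR length, still apart. The 5 targets or seed-site genes lowest with native let-7a were all higher with the methylated form. They were SLC5A3_1 (16.4 against 9.6 TPM), C8orf58 (16.1 against 8.9 TPM), HMGA2 (28.1 against 23.9 TPM), RIMKLA (5.7 against 4.2 TPM) and the hexokinase HK2 (59.3 against 38.5 TPM). These genes were chosen for low values in the native library, which alone would favour a higher value in the other.

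The 2 let-7a libraries also differed in genes outside the target lists. All 31 hypoxia and glycolysis genes were higher with methylated let-7a, with the list at 0.47, ANGPTL4 at 32.8 against 12.7 TPM and SLC2A1 at 406.1 against 235.7 TPM. All 34 G2/M genes were lower, with the list at -0.23 and the kinesin KIF23 at 33.4 against 45.4 TPM, and G1/S genes lay at -0.11. ATF4 and unfolded protein response genes lay at -0.16, with CHAC1 at 63.9 against 104.2 TPM, p53 targets at -0.08, nuclear oxidative phosphorylation genes at -0.04 and immediate early genes at -0.06. The mitochondrially encoded mRNAs lay at 0.26, microRNA host genes at 0.09, Wnt and stem-like genes at 0.08, heat shock genes at 0.08, epithelial adhesion genes at 0.07, with ELF3 at 109.4 against 86.5 TPM, and ribosomal protein genes at 0.07. Across genes, the difference was larger with longer 3′ UTRs (Spearman's rho 0.18 over 12002 genes, which are not independent). The 2-fold rule counted 133 genes higher and 138 lower.

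**Figure D1:**
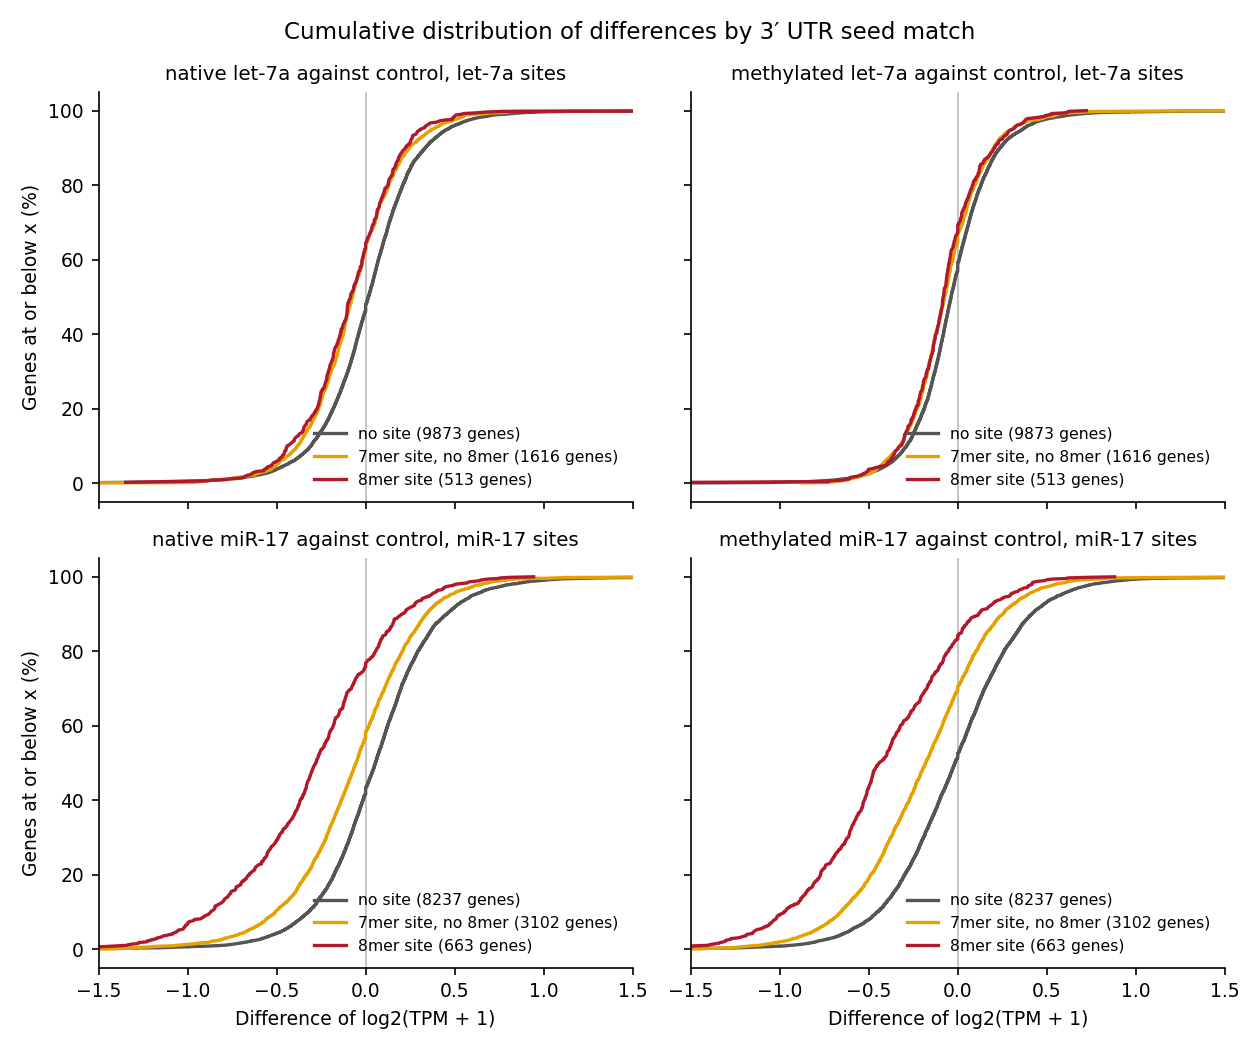
Cumulative distributions, over 12002 genes, of the difference of log2(TPM + 1) between each microRNA library and the control (x axis), as the percentage of genes at or below each value (y axis), for genes without a site, with a 7mer site and with an 8mer site of the transfected microRNA. The miR-17 curves are ordered by site class, with medians of 0.055, -0.054 and -0.279 for no site, 7mer and 8mer with native miR-17, and the let-7a curves lie closer together, with medians of 0.015, -0.074 and -0.085 with native let-7a.

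Native miR-17 against the control gave the larger response of its seed-site genes. LIMK1, a kinase that regulates the actin cytoskeleton, went from 60.7 to 22.3 TPM, ENPP5 from 28.5 to 10.7 TPM, PFKP, the platelet-type phosphofructokinase, from 160.7 to 52.1 TPM, and the antiproliferative gene BTG3 from 58.4 to 24.4 TPM. Of the 57 known miR-17 targets tested, 55 were lower and 13 of them at least 2-fold, and the list lay at -0.63. E2F3 (29.2 against 26.8 TPM) and RBL1_1 (4.7 against 4.6 TPM) were the 2 members not lower. With the let-7a libraries as reference the list lay at -0.51, and LIMK1 and ENPP5 had 61.9 and 31.2 TPM with native let-7a. Genes with a miR-17 seed site, 3765 of those searched, lay at -0.09, and at -0.07 with 3′ UTR length matched. The median difference was 0.06 for genes without a site, -0.05 for a 7mer site and -0.28 for the 663 genes with an 8mer site. Of the 8mer genes, 46 were at least 2-fold lower and 0 at least 2-fold higher. Of the 141 searched genes that were at least 2-fold lower, 87 had a miR-17 site (61.7%, against 31.4% of all searched genes).

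Cholesterol synthesis genes were lower with native miR-17, 22 of 24 members, with the list at -0.56, whereas the list lay at -0.005 and -0.001 in native and methylated let-7a. The sterol oxidase MSMO1 went from 231.1 to 99.8 TPM and mevalonate kinase MVK from 39.0 to 16.6 TPM. These 2 genes each have a miR-17 site, as do 5 of the 24 list members (20.8%, against 33.1% of all searched genes, counting any annotated 3′ UTR). Hypoxia and glycolysis genes lay at -0.94, with 30 of 31 lower, and included PFKP, ANGPTL4 (11.3 TPM) and CA9 (0.2 TPM). Immediate early genes lay at -0.36, with the transcription factors KLF2 (78.6 to 28.5 TPM) and FOSL1 (148.6 to 75.5 TPM). The TGF-beta response lay at -0.19, with BAMBI at 28.3 TPM. Heat shock genes lay at -0.23, with HSPA8 at 601.9 against 1109.8 TPM. Other genes of at least 20 TPM with large decreases were F3, the tissue factor that starts coagulation (log2 difference -1.52), and the growth factor EREG (684.1 to 257.1 TPM).

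Cell-cycle genes moved in opposite directions with native miR-17. G1/S and DNA replication genes lay at 0.30, with 29 of 38 higher, such as the polymerase subunit POLA1 (6.5 to 12.4 TPM) and the licensing factor CDC6 (24.4 to 38.9 TPM). G2/M genes lay at -0.32, with 33 of 34 lower, such as KIF23, which has an 8mer site (36.6 to 16.9 TPM), NEK2 (58.2 to 40.2 TPM) and ANLN (74.7 to 53.4 TPM). ATF4 and unfolded protein response genes lay at 0.25, with CHAC1 at 133.0 TPM and ASNS at 386.8 TPM. Interferon-stimulated genes lay at 0.25, with 25 of 29 higher, IFIT3 at 14.9 against 5.1 TPM and BST2 at 16.8 against 6.7 TPM. Nuclear oxidative phosphorylation genes lay at 0.16, ribosomal protein genes at 0.07, colon differentiation genes at 0.37 with 5 tested, 3 of them higher, including KRT20 (8.3 to 11.3 TPM), and 2 lower (mean log2 difference 0.125), and mitochondrially encoded mRNAs at -0.30. SPARC, a matrix protein typical of mesenchymal cells, had 44.7 TPM with native and 38.7 TPM with methylated miR-17, against 8.2 TPM in the control, while the mesenchymal list stayed within the random lists in both (-0.12 and -0.13). With the let-7a libraries as reference, the ATF4 (-0.02), ribosomal protein (-0.02), oxidative phosphorylation (0.05), TGF-beta (-0.02) and mitochondrially encoded (-0.03) lists were no longer apart. The rule of size counted 238 genes higher and 242 lower.

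**Figure D2:**
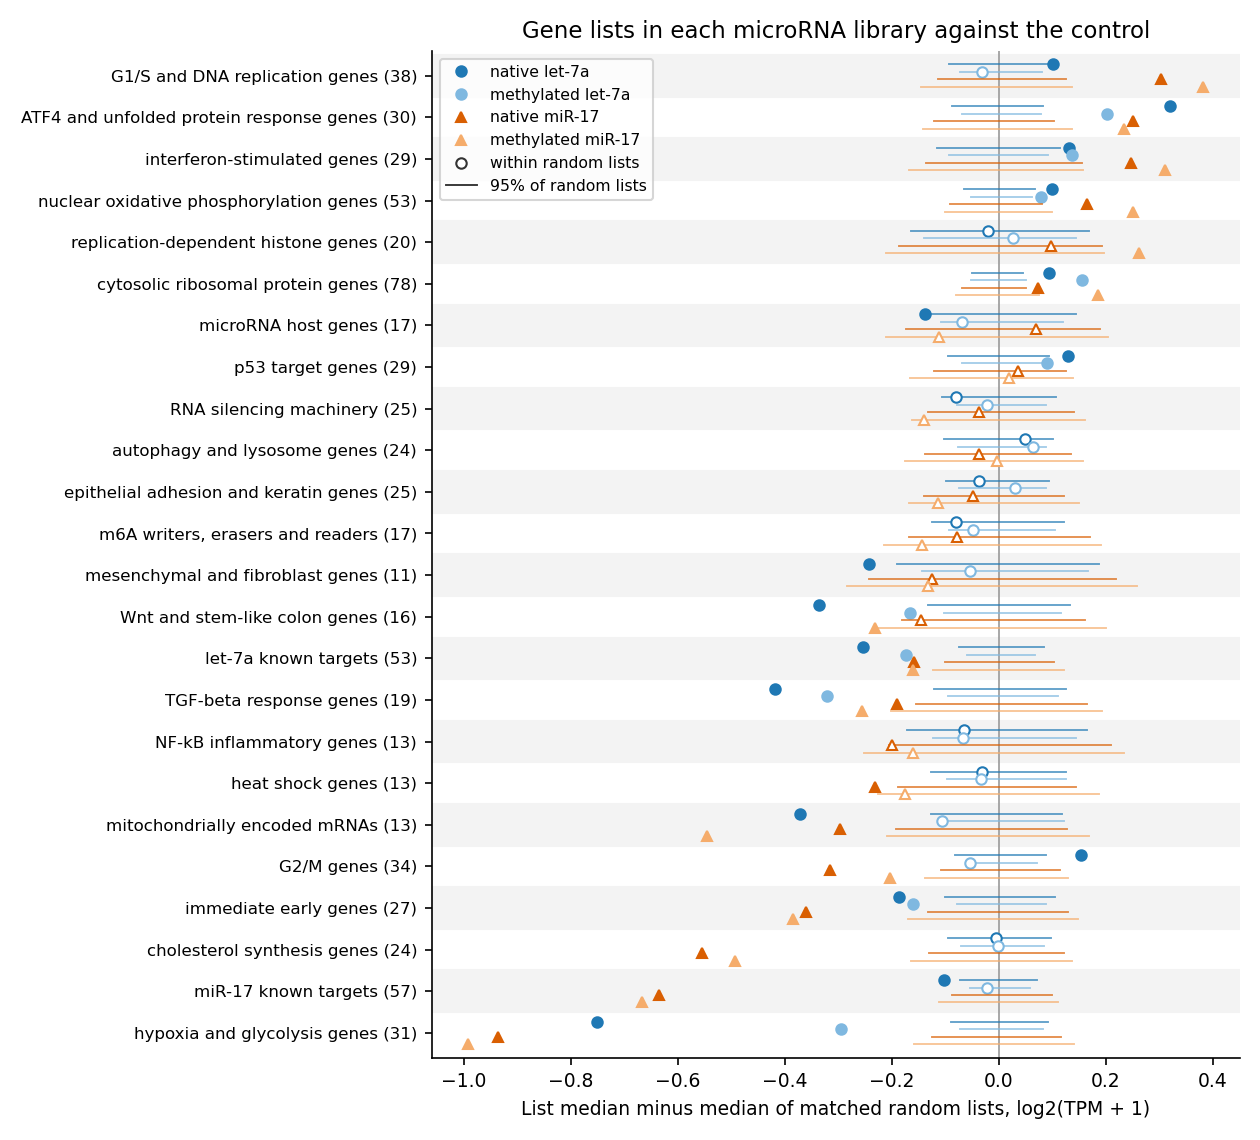
Median difference of each gene list from the control minus that of matched random lists, in log2(TPM + 1) (x axis), for the lists with at least 10 tested members (numbers tested in parentheses, y axis), with 1 point per microRNA library. Thin lines span 95% of the random lists, and open points lie within them; hypoxia and glycolysis genes were the lowest list in native miR-17 at -0.94, and cholesterol synthesis genes lay at -0.56 in native miR-17 and near 0 in both let-7a libraries.

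Methylated miR-17 against the control showed the same named targets at similar levels. LIMK1 had 19.5 TPM, ENPP5 9.1 TPM, PFKP 56.8 TPM and FYCO1, an autophagosome transport adaptor, 8.2 TPM against 21.7 TPM. Of the known targets 56 of 57 were lower, 17 at least 2-fold, and the list lay at -0.67. Genes with a miR-17 site lay at -0.12, and at -0.065 with 3′ UTR length matched. The 8mer genes had a median of -0.44, against -0.02 for genes without a site, and 61 were at least 2-fold lower and 0 higher. These values are not matched on 3′ UTR length. In the heptamer model, which holds it, GCACTTT had coefficients of -0.1736 in native and -0.1579 in methylated miR-17 against the control. A miR-17 site was present in 123 of the 193 searched genes at least 2-fold lower (63.7%). Cholesterol synthesis genes lay at -0.49, with MSMO1 at 102.5 TPM, hypoxia and glycolysis genes at -0.99, immediate early genes at -0.38, TGF-beta response genes at -0.26, Wnt and stem-like genes at -0.23 and G2/M genes at -0.20. G1/S genes lay at 0.38, with MCM5 at 28.3 against 16.6 TPM, interferon-stimulated genes at 0.31, nuclear oxidative phosphorylation genes at 0.25, ATF4 and unfolded protein response genes at 0.23, ribosomal protein genes at 0.19, replication-dependent histones at 0.26 and colon differentiation genes at 0.46, with 3 of 5 higher and a mean log2 difference of 0.014. Mitochondrially encoded mRNAs lay at -0.55. With the let-7a libraries as reference, ATF4 and unfolded protein response genes were apart in the opposite direction (-0.12), and TGF-beta (0.05) and Wnt (-0.07) genes were no longer apart. With a mean of at least 5 TPM, the histones (0.24) and Wnt genes (-0.21) were within the random lists. There were 184 genes at least 2-fold higher and 335 lower. The median of all genes was -0.065 in this comparison, and rescaling to protein-coding genes placed the median of 12236 such genes at -0.12 here and at -0.11 in methylated against native miR-17.

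Methylated against native miR-17 asked the same question of the second microRNA. The known targets lay at -0.05, at percentile 2.76, within the random lists, but were apart with a pseudocount of 5 (-0.04) and with a mean of at least 5 TPM (-0.05), and 42 of 57 were lower in a comparison where the median of all genes was -0.09. BTG3 (29.2 against 24.4 TPM) and KPNA2 (280.9 against 240.7 TPM) were the highest members and PKD1 (6.3 against 8.2 TPM) the lowest. Among the targets or seed-site genes lowest with native miR-17, PRR15 was higher with the methylated form (7.9 and 5.2 TPM, log2 difference 0.52) and the others named here differed little, with CYBRD1 at 7.0 and 6.8 TPM, F3 at a log2 difference of 0.12 and PFKP at 56.8 and 52.1 TPM. Genes with a miR-17 site lay at -0.02, and they lay at 0.007 with random lists matched on 3′ UTR length, apart in the opposite direction (percentile 99.9). Across genes, the difference was lower with longer 3′ UTRs (Spearman's rho -0.34, the largest of the 6 comparisons), and the lowest genes of at least 20 TPM included the chromatin regulators KMT2D (15.1 against 23.9 TPM) and ARID1A (23.9 against 36.2 TPM). All 78 ribosomal protein genes were higher, at 0.10, and all 13 mitochondrially encoded mRNAs lower, at -0.29.

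Other lists were apart in methylated against native miR-17. Histones lay at 0.16, G2/M genes at 0.10, G1/S genes at 0.10, nuclear oxidative phosphorylation genes at 0.09, hypoxia and glycolysis genes at 0.07, and interferon-stimulated genes at 0.08 although their own median was -0.03. Wnt and stem-like genes lay at -0.12, TGF-beta response genes at -0.10, RNA silencing machinery at -0.09, with AGO2, the slicing Argonaute, at 27.1 against 34.5 TPM, ATF4 and unfolded protein response genes at -0.09, epithelial adhesion genes at -0.08 and p53 targets at -0.07. The let-7a target list lay at -0.06. With a mean of at least 5 TPM, the histones (0.12), Wnt (-0.08) and interferon-stimulated genes (0.06) were within the random lists. The 2-fold rule counted 94 genes higher and 138 lower.

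**Figure D3:**
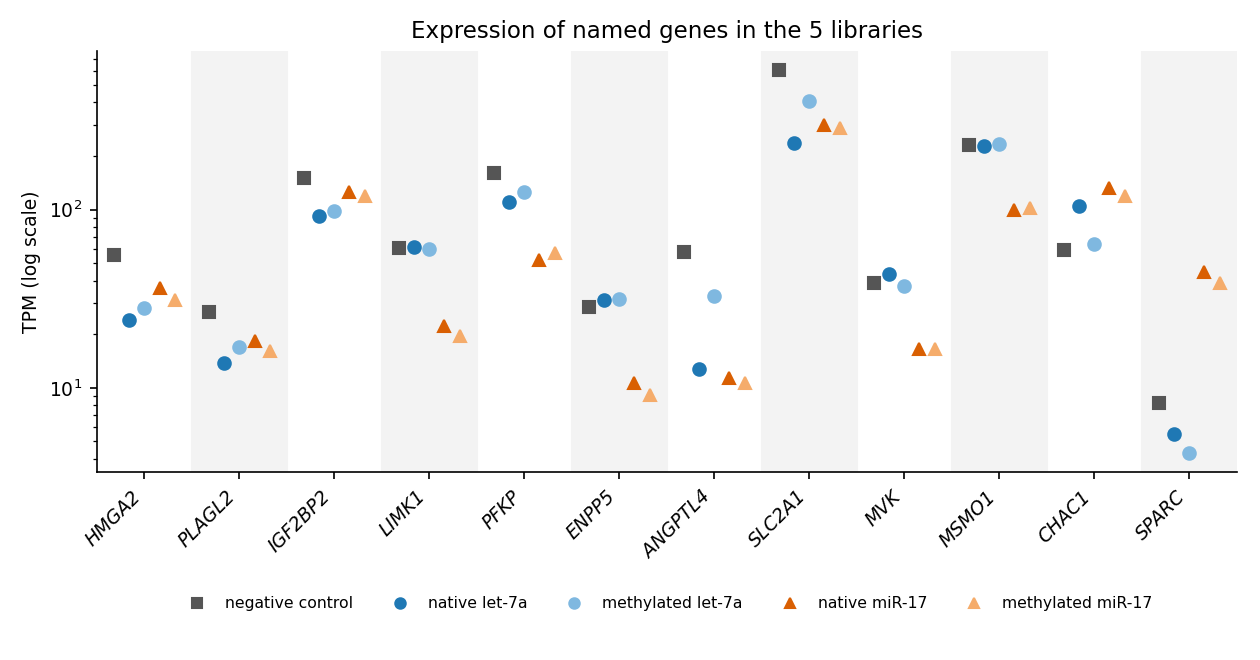
TPM of 12 named genes (y axis, log scale) in the 5 libraries, with 1 point per library and no replicates. LIMK1, ENPP5, MVK and MSMO1 are low in both miR-17 libraries, and HMGA2 lies at 56.0 TPM in the control and 23.9 to 36.5 TPM in the microRNA libraries.

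Lists that were apart in none of the 6 comparisons included the m6A writers, erasers and readers, between -0.14 and 0.04, the autophagy and lysosome genes, between -0.04 and 0.06, and the NF-kB inflammatory genes, between -0.20 and 0.08. The markers of blood and immune cells, with 5 tested, lay between -0.06 and 0.13, and of the endothelial markers 1 was tested, at -0.22 to 0.35. RNA silencing machinery was within the random lists in each comparison against the control (-0.14 to -0.02).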

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

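Both tests of the pattern weighed here were written before their values were computed, while the pattern itself was chosen after the result was seen. The results below were picked out because the methylated form differed from the native form in opposite directions for let-7a and miR-17, a difference that was not tested and that rests on 1 library per group. Values are list medians relative to random lists (log2), let-7a first. Genes with the microRNA's own seed site lay at 0.036 and -0.025, known let-7a targets at 0.152 and -0.061, G1/S genes at -0.108 and 0.099, and G2/M genes at -0.227 and 0.1. Mitochondrially encoded mRNAs lay at 0.263 and -0.287, nuclear oxidative phosphorylation genes at -0.044 and 0.093, Wnt and stem-like colon genes at 0.083 and -0.118, and epithelial adhesion genes at 0.074 and -0.079. With 3′ UTR length matched, the own-site values were 0.016 and 0.007, so the opposite directions there depended on 3′ UTR length.

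Relative to random lists, genes with a let-7a seed site were less lowered by methylated than by native let-7a, although their own median against the control was -0.076 in both. 3′ UTR length alone was excluded as the explanation, since these genes lay at percentile 100 of random lists matched on it. A difference between the 2 let-7a libraries that is not specific to the let-7a seed could not be told apart, because CTACCTC ranked 86 from the highest of 16384 heptamers, between the limits of 16 and 164 set for the test. The other let-7a match, TACCTCA, which the test did not name, ranked 2. Rank 1 was GGAGGGG, which is not a let-7a match and had ranked 2 from the lowest with native let-7a against the control. A high rank here was therefore not particular to let-7a matches. Both let-7a matches had positive coefficients (0.0163 for CTACCTC and 0.0266 for TACCTCA), and of these only TACCTCA was within the limit of 16. Genes with a miR-17 site were also higher (0.014, percentile 100). With 3′ UTR length, GC content and expression in the model, however, GCACTTT had a coefficient of -0.0071. A weaker action of the methylated form is 1 possibility, and 1 library of each form cannot separate it from unequal transfection.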

How the results depend on the processing

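With 1 library per group and unknown depth, no replicate could be left out and no other split made, and no paired analysis was possible because the libraries share no number. Of the values that answer a comparison, 128 stayed the same under an alternative, 40 moved, 6 turned, 4 became weaker and 2 stronger. For a count of genes, the same meant a total within 1.5-fold of the main one. For a list or seed-site value, it meant that the call against random lists and its direction stayed. Counts of genes at least 2-fold different depended on the settings below. In the order native let-7a, methylated let-7a, methylated against native let-7a, native miR-17, methylated miR-17, and methylated against native miR-17, they were 626, 526, 493, 825, 907 and 433 with a pseudocount of 0.1, and 80, 42, 43, 124, 137 and 33 with 5. They were 585, 546, 515 and 721, and 470 in the last, with no filter, 111, 74, 46, 232, 253 and 51 with a mean of at least 5 TPM, and 132, 98, 80, 275, 340 and 80 for protein-coding genes without mitochondrial genes. At 1.5-fold they were 1141, 894, 635, 1762, 2189 and 588. For genes above 0 in all 5 libraries, added after the data were seen, they were 203, 164 and 126 for let-7a and 113 for methylated against native miR-17. Each of these settings changes by construction the values, the genes or the threshold that the count rests on, and no further cause was tested. Known miR-17 targets in methylated against native miR-17 passed the threshold at -0.043 with a pseudocount of 5 and at -0.053 with a mean of at least 5 TPM, and the cause was not tested. With 3′ UTR length matched, miR-17 seed-site genes turned to 0.007 in that comparison, and to 0.011 for 8mer sites (added), both apart in the opposite direction, so the direction there depends on 3′ UTR length.

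The seed of the 3p arm with 3′ UTR length matched (added) searches other sites, and the values that changed under it were near 0. They were -0.004 in native let-7a and -0.001 in methylated against native let-7a. For miR-17 they were 0.003 (native), 0.006 (methylated) and -0.004 (methylated against native). Methylated let-7a against the control is not among them, as its call and direction did not change. Without length matching, no value for the 3p seed was among those that changed. These values therefore do not show that 3p sites stayed within the random lists. With the other microRNA's libraries as reference, methylated miR-17 had 320 genes at least 2-fold different, let-7a seed-site genes lay at -0.005 in methylated let-7a, and known let-7a targets at -0.039 and 0.061. In the same setting, added for the other lists, native and methylated let-7a turned to -0.166 and -0.207 for interferon-stimulated genes, -0.094 and -0.109 for nuclear oxidative phosphorylation, 0.072 and 0.361 for mitochondrially encoded mRNAs, 0.528 and 0.554 for cholesterol synthesis, 0.082 and 0.588 for hypoxia, 0.141 and 0.245 for heat shock, and 0.252 and 0.271 for immediate early genes. Native let-7a turned to -0.197 for G1/S, -0.055 for ribosomal protein and 0.02 for TGF-beta genes, and methylated let-7a to 0.202 for G2/M, -0.23 for histone, -0.005 for ATF4 and 0.08 for Wnt genes. Native miR-17 turned to -0.022 for ribosomal protein and -0.02 for ATF4 genes, and methylated miR-17 to -0.121 for ATF4 and 0.053 for TGF-beta genes. Of named genes, native let-7a turned for ANGPTL4 (0.192), CA9 (0.415), LOXL2 (0.234), BNIP3 (0.079), MNAT1 (-0.125) and CANX (-0.039), methylated let-7a for MNAT1 (-0.159), native miR-17 for ST20-MTHFS (-0.05), and methylated miR-17 for CTB-59C6.3 (-0.428), ST20-MTHFS (-0.328), HIST1H2AJ (-0.378), CACUL1 (-0.2) and CANX (-0.106). By construction this reference holds the other microRNA's own changes. Of the list and gene values, 38 turned, all with that reference and printed above, 2152 stayed the same, 29 became weaker, 11 stronger and 270 moved.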

Other observations

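Several genes outside the fixed lists differed strongly in the miR-17 libraries. DKK1, a secreted Wnt antagonist, had 97.1 TPM in the control, 155.3 with native let-7a, 98.4 with methylated let-7a, 41.7 with native miR-17 and 43.4 with methylated miR-17. FOXD1, a forkhead transcription factor, had 22.7, 20.7, 17.1, 0.9 and 9.6 TPM in the same order. Of the 31 hypoxia and glycolysis genes, the 28 without a let-7a site lay at -0.73 with native let-7a, and the 20 without a miR-17 site at -0.814 with native miR-17. Both tests of this pattern were chosen after it was seen. Own sites do not account for the members without them, while the control standing apart is left open as a part of the pattern. With the miR-17 libraries as reference, native let-7a lay at 0.082, no longer apart, but methylated let-7a lay at 0.588. The list also lay at 0.471 between the 2 let-7a libraries. These last 2 differences do not involve the control, so it cannot account for them.

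Of the tests below, that of the let-7a reference, the rank of GGTTGTG in a set of 6001 genes and that of its 8-mer were chosen after the result was seen, the last in place of an earlier one that mixed genes with 2 different 7-mers, and the heptamer model was itself added after the data were seen. Genes with a miR-17 seed site were lower in both miR-17 libraries than in the control. 3′ UTR length, GC content or expression level was excluded as the explanation, as GCACTTT had rank 1 from the lowest of 16384 heptamers in native miR-17 with these properties in the model. The control library alone was excluded too, as these genes lay at percentile 0.0 with the let-7a libraries as reference. Seed-directed lowering by both forms was favoured, as GCACTTT also had rank 1 in methylated miR-17.

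The heptamer GGTTGTG was in the 3′ UTR of 1247 of the genes searched. Relative to other genes, these were lower in the control than in the mean of the 4 microRNA libraries. Their own median was -0.01. They included CACUL1, MNAT1, CANX and SLC7A11, the last named above with the ATF4 and unfolded protein response genes. With 3′ UTR length, GC content and expression level in the model, GGTTGTG was the lowest heptamer in a random set of 6001 genes. It had rank 1 from the lowest in the other 6001 (coefficient -0.1296). The difference thus remained with terms for these properties. However, GGTTGTG had been picked as the top of this model over all the searched genes, so high ranks in both sets were likely beforehand. The split therefore cannot exclude these properties as the cause. Sites of let-7a or miR-17 were excluded, as the 443 GGTTGTG genes with neither site lay at -0.088 in the control minus the mean of the 4. The hypothesis that the control oligonucleotide carries the seed CACAACC was favoured. Among GGTTGTG genes, the 321 with the 8-mer GGTTGTGA lay at -0.058, matched on expression, 3′ UTR length and GC content. The 1798 genes with GGTTGTG or GTTGTGA and no 8-mer had an unmatched median of 0.036, against 0.032 for genes with neither. Matched on expression and 3′ UTR length, the 926 of them with GGTTGTG lay at -0.066 (percentile 0.0). The other 872 lay at -0.024 (percentile 0.3). For genes without the 8-mer, the difference thus appeared only with this matching. The nematode microRNA cel-miR-67, a common negative-control mimic, has the seed CACAACC, but the labels give no control sequence and the hypothesis rests on 1 control library.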
